A study of Mus musculus with 12 samples.

How the data were processed

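RNA was measured in 12 samples, 3 in each of 4 groups: GFP+ and GFP- fibroblasts sorted from stromal vascular cultures of inguinal or epididymal fat of Zfp423-GFP transgenic male mice on an FVB and C57BL/6 background. Per the labels and the series record the sorted cells were returned to culture and harvested below confluence, RNA was extracted with Trizol and an RNeasy column, and biotin-labelled cRNA was hybridised to Affymetrix arrays. The deposited values are probe set intensity on a linear scale, from the series' value table. The signal algorithm, background correction, scaling and software were not given in the sources used here. Array medians lay within 0.1 of each other on the log2 scale, so no further normalization was applied. The largest value was 46213. Scanner files were not analysed here.

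The table held 22626 probe sets, none of them a control probe set. The platform annotation gave 1 gene symbol for 20380, several for 691 and none for 1555; only the first kind was used. Symbols were updated through Entrez identifiers with the RefSeq gene table of assembly GRCm38.p6, and 29 symbols had no current match and were kept as given. No coordinates were used. Values were transformed to log2(intensity + 16), and the probe set with the highest mean over all arrays stood for its gene, which left 12393 genes. Genes in the lowest 30% of means (under log2 6.55, an intensity of 77.7) were called weakly detected and kept. With this pseudocount fold changes of such genes are understated.

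Groups came from the sample labels. The contrasts were GFP+ against GFP- in each depot, their difference (interaction), and inguinal against epididymal in GFP+ and in GFP- cells. Each was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on mean expression) over all 12 arrays, with Benjamini-Hochberg adjustment at 0.05 over all genes. Genes called in both depots were counted per direction and set against independent calls with Fisher's exact test. On simulated data for 12393 genes the inguinal GFP contrast recovered 55.2%, 89.6% and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale, with 6.38% false calls. The epididymal contrast recovered 62.7%, 82.1% and 98.5% with 8.38% false calls. Each simulation was drawn once, with independent normal noise, 66 or 67 changed genes per size and a shifted list of 20 genes. The real contrasts called 12.6% and 41.9% of genes, and real genes are correlated, so these rates need not hold for them. The number of arrays limits the precision.

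Gene lists were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. The 20 lists held 499 genes, of which 455 were measured: adipogenic regulators, anti-adipogenic regulators, adipocyte lipid genes, brown and beige fat genes, fibroblast progenitor markers, extracellular matrix genes, BMP and TGF-beta pathway genes, Wnt pathway genes, depot position genes, inflammatory genes, interferon response genes, cell cycle genes, bone and cartilage genes, sex check genes, and markers of macrophages and leukocytes, endothelial cells, mural cells, mesothelial cells, epithelial cells, and skeletal muscle and Schwann cells. They were tested with camera (preset correlation 0.01), adjusted over the lists of a comparison, and again with an estimated correlation. Lists of retinoid genes, imprinted genes, IGF axis genes and further macrophage genes were chosen after the leading genes were seen and appear only in the closing section.

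The rule for named genes took Zfp423; per comparison the 8 genes with the largest called change in each direction whose groups did not overlap and whose higher mean was not weakly detected; per list and comparison up to 4 called members with the smallest adjusted p, or up to 2 uncalled members; the 6 interaction genes with the smallest p; the 8 genes per direction with the largest smaller change shared by both depots; and the sex check genes. It named 202 genes in 382 pairs of gene and comparison. For length, the text names part of them, and that part was chosen after the values were seen. A first choice left out many genes whose calls changed with the processing, and most of these were then added. As it stands, 18 of the 206 pairs of the rule that are in the text changed side of the threshold under at least 1 alternative, against 7 of the 176 that are not.

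Alternatives were the replicate number as a block, quantile normalization, median centring, pseudocounts of 1 and 64, weakly detected genes left out, only the groups compared in the fit, no variance trend, array weights, every probe set or the mean of a gene's probe sets, a minimum change of 1.5-fold, an adjusted p of 0.01, and each array left out in turn. For lists they were an estimated correlation, fry, quantile normalization, the block, weakly detected genes left out and each array left out. Counts without the leukocyte lists or the mesothelial list were added after the data were seen. The tests of a second macrophage list and of a lower fibroblast share were set to undecided after their values were seen, the first because its list holds leading genes, the second because most comparator markers were weakly detected.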

Results

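Gene expression was measured on 12 Affymetrix arrays from cultured mouse fibroblasts. The cells came from the stromal vascular fraction of fat, which is what remains of the tissue once the fat cells are removed, and were taken from the inguinal depot under the skin or from the epididymal depot inside the abdomen. The donors were male Zfp423-GFP transgenic mice aged 6 to 8 weeks. Zfp423 is a zinc-finger transcription factor known to commit fibroblasts to the fat lineage, and green fluorescent protein (GFP) was used to sort cells into a positive and a negative population. The sorted cells went back into culture and, per the labels, were harvested before growth arrest. The series asks which genes mark the preadipocyte fibroblasts of each depot. There were 4 groups of 3 arrays: inguinal GFP+, inguinal GFP-, epididymal GFP+ and epididymal GFP-. The number of arrays per group limits the precision. No label says that replicates came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

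The arrays carried 22626 probe sets, and 12393 genes were tested. Median signal ranged from 347.3 in inguinal GFP+ replicate 2 to 371.2 in epididymal GFP+ replicate 2. Arrays of the same group correlated across genes at r between 0.993 and 0.995, a description only, since genes are not independent replicates. The first principal component held 59.3% of the variance and ordered the arrays from inguinal through epididymal GFP+ to epididymal GFP-. The second held 16.5% and set epididymal GFP+ apart. The labels give male mice, and the Y-linked gene Eif2s3y was bright in all groups (mean signal 3371, 3246, 2789 and 2912 in inguinal GFP+, inguinal GFP-, epididymal GFP+ and epididymal GFP-). Xist, expressed from the inactive X chromosome of females, read between 42.8 and 80.9 in the group means.

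**Figure D1:**
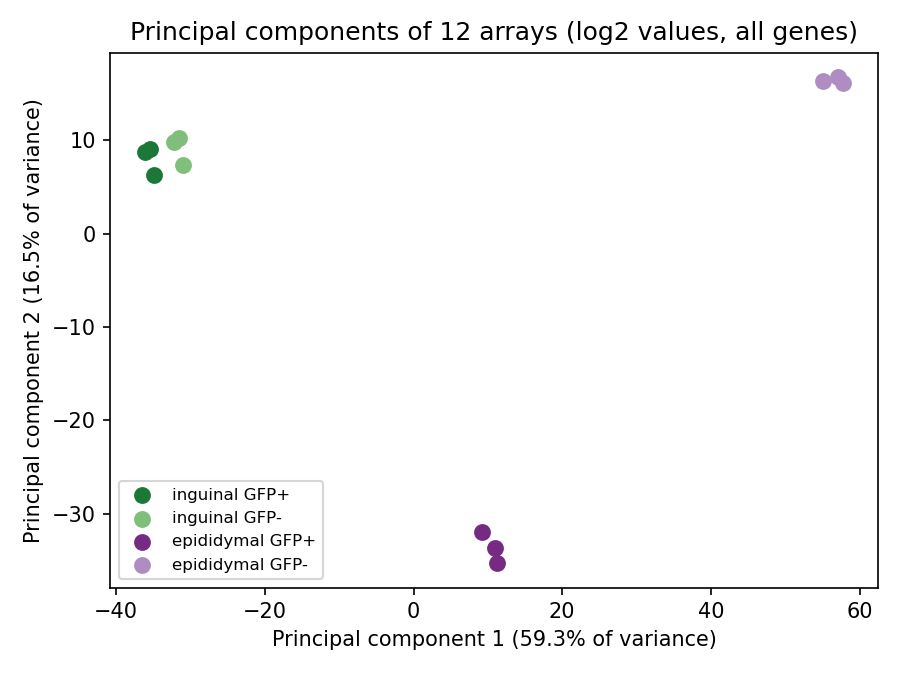
Principal components of the 12 arrays, computed on log2 values of all genes; each point is an array, coloured by group, and the axes give the component scores with the percentage of variance (59.3% and 16.5%). The inguinal GFP+ and GFP- arrays lie close together, and the epididymal GFP+ and GFP- arrays lie far apart.

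Zfp423 itself followed the sort in both depots. Its mean signal was 124 ± 22.9 (SD, n = 3) in inguinal GFP+ and 57.4 ± 13.8 in inguinal GFP-, a log2 fold change of 0.94 ± 0.18 (SE; adjusted p = 0.00198, limma with Benjamini-Hochberg adjustment). In the epididymal cultures it was 242 ± 35.1 in GFP+ and 29.4 ± 3.80 in GFP-, a log2 fold change of 2.50 ± 0.18 (adjusted p = 8.53e-09). The depots differed in this contrast by -1.56 ± 0.26 (adjusted p = 0.000138). Pparg and Fabp4 rose with Zfp423 in both depots. Pparg, the nuclear receptor that drives fat cell differentiation, rose by 1.28 in inguinal and 2.17 in epididymal GFP+ cells, and Fabp4, a fatty acid carrier of fat cells, by 1.81 and 4.30. All these fold changes are on the log2(signal + 16) scale, which understates the change of weakly detected genes. Genes of families silent in fibroblasts, such as olfactory receptors, had a median signal between 17.5 and 21.4 in the 4 groups. Where the lower group lies near that level, the fold change and its rank depend on the array floor and the pseudocount. The lower group was weakly detected (signal under 77.7) for 10 of the 16 leading genes in inguinal cultures, 7 of 16 in epididymal cultures, 11 of 16 between depots in GFP+ cells and 14 of 16 in GFP- cells.

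**Figure D2:**
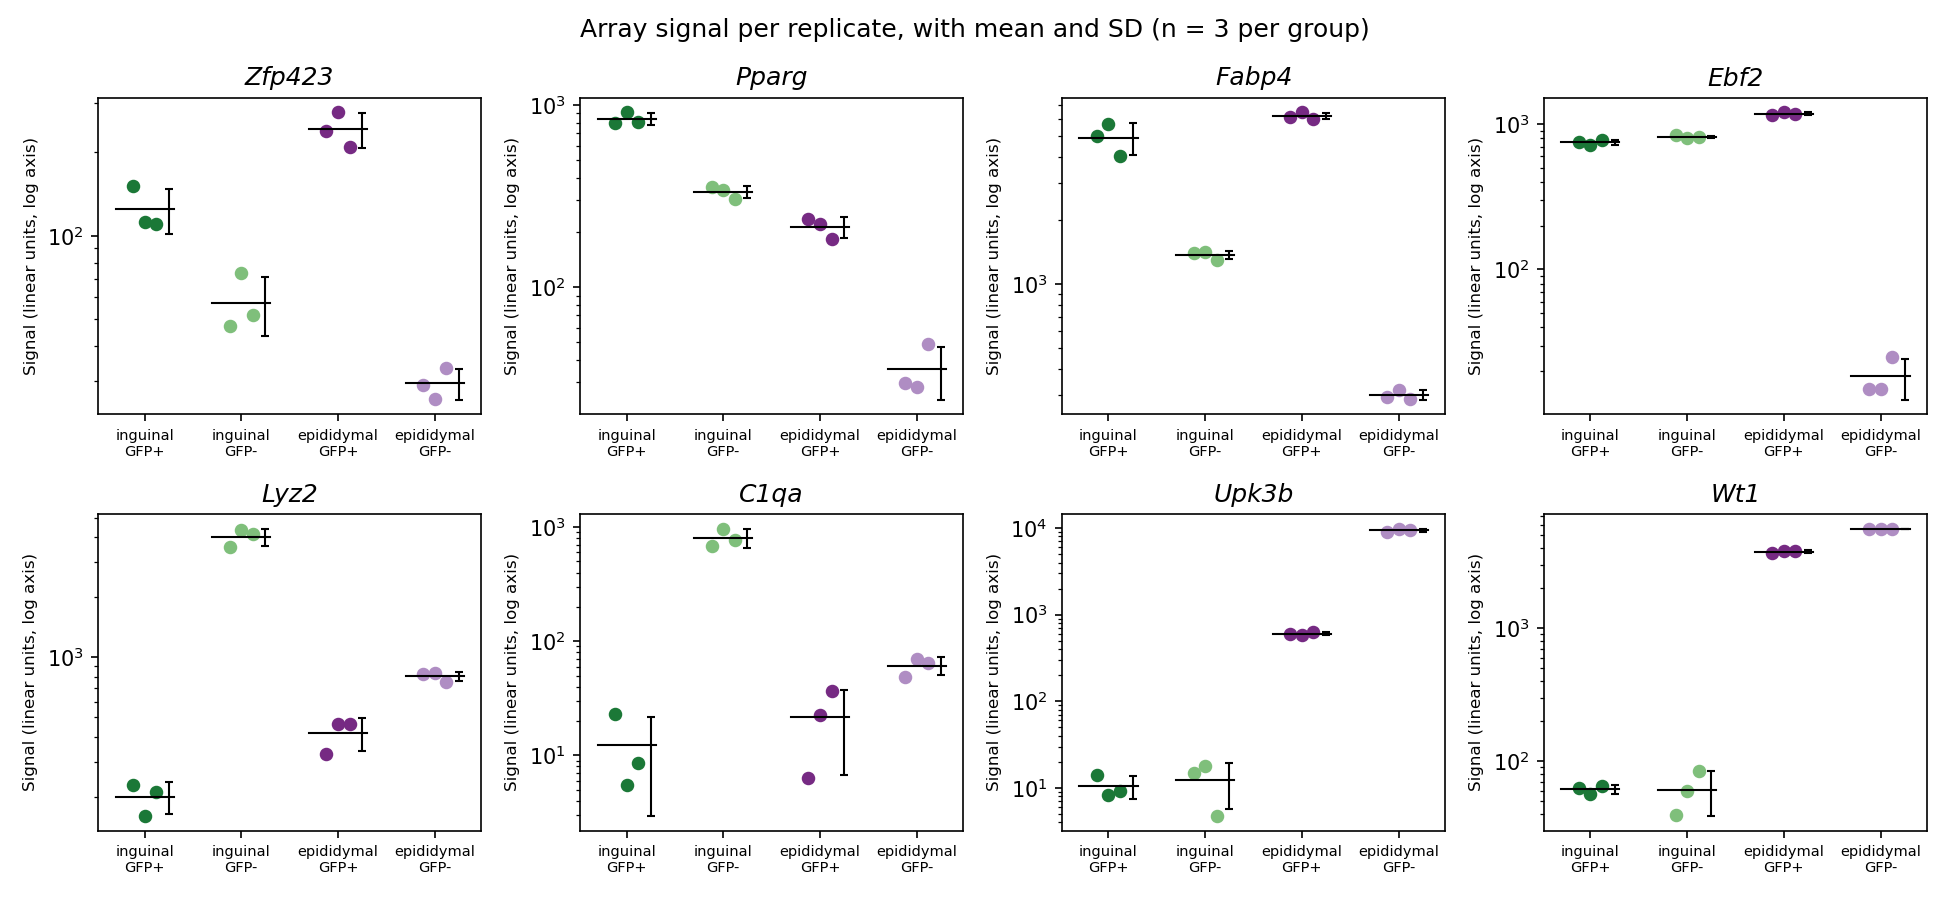
Array signal of 8 genes per replicate on a log axis in linear signal units; points are arrays, horizontal lines the group means and vertical bars the SD (n = 3). Zfp423, Pparg and Fabp4 were higher in GFP+ than in GFP- cells of both depots; Ebf2 was near 18.4 in epididymal GFP- cells only; Lyz2 and C1qa peaked in inguinal GFP- cells; Upk3b peaked in epididymal GFP- cells, and Wt1 was above 3700 in both epididymal groups.

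In inguinal cultures, GFP+ cells carried far less of the macrophage transcripts found in GFP- cells, and more of Mrap, Sfrp2, Rspo2, Dpt and other single genes. The 8 largest increases were Mrap (3.44 ± 0.16), the accessory protein of the melanocortin receptors, Sfrp2 (2.57 ± 0.34) and Rspo2 (2.54 ± 0.17), secreted modulators of Wnt signalling, Dpt (2.45 ± 0.24), a matrix protein, Trpc6 (2.19), a cation channel, Ggt5 (2.18), a gamma-glutamyl transferase, the matrix protein Spon1 (2.07), and the oxysterol hydroxylase Cyp7b1 (2.02). Mrap signal was 470 ± 50.8 in GFP+ and 29.4 ± 9.46 in GFP- cells. The 8 largest decreases were all genes of macrophages: the complement genes C1qa (-4.90 ± 0.29), C1qc (-4.12) and C1qb (-3.70), the lysozymes Lyz1 (-4.32) and Lyz2 (-4.22 ± 0.13), the protease Ctss (-4.63), the pore protein Mpeg1 (-4.21) and the signalling adaptor Tyrobp (-3.56). Lyz2 signal was 4011 ± 400 in inguinal GFP- and 201 ± 36.4 in inguinal GFP+ cells. Probe sets of Lyz1 disagreed: another bright one gave -4.42, and a weakly detected one (mean log2 5.21) gave -0.08. In total 1556 of 12393 genes passed an adjusted p of 0.05 in limma, 652 higher and 904 lower in GFP+, of which 50 and 118 changed by at least 2-fold. The balance depends on the scaling, with 773 higher and 725 lower after median centring and 749 and 807 after quantile normalization.

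Of the 21 measured macrophage and leukocyte markers, 15 fell, 0 rose and 6 were not called (19 fell adjusted over the list alone). The list as a whole was lower relative to other genes (camera, preset correlation, adjusted p = 4.01e-26), and this held with an estimated correlation (adjusted p = 0.000844). Of 20 mural cell markers, genes of pericytes and smooth muscle, 10 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 2.52e-06; adjusted p = 0.0219 with an estimated correlation). Examples were Mcam (-1.36), the smooth muscle myosin Myh11 (-1.0), smoothelin, Smtn (-0.64), and the smooth muscle actin Actg2 (-0.60). The other marker lists of cells that a sort can carry along moved little, but many of their genes could hardly fall. Weakly detected over all arrays were 13 of 19 endothelial, 11 of 15 epithelial and 9 of 13 skeletal muscle and Schwann cell markers. The median signal of mesothelial markers in inguinal GFP- cells was 57.7. These lists are thus weak evidence on such cells. Of 19 endothelial markers 2 rose and 1 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.773). Egfl7 was among the increases (0.57, adjusted p = 0.0405) and endoglin, Eng, was the decrease (-0.21, adjusted p = 0.0462); with the mean of all probe sets of a gene Egfl7 gave 0.02 (adjusted p = 0.967) and Eng -0.13 (adjusted p = 0.309), neither called. Of 15 mesothelial markers 2 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.773). The increases were the keratin Krt7 (1.82) and the transcription factor Bnc1 (0.96), which was weakly detected (66.7 in GFP+ and 26.7 in GFP- cells). The decreases were Efemp1 (395 in GFP+ and 676 in GFP- cells) and Nkain4 (45.9 and 93.9). Of 15 epithelial markers 1 rose, and of 13 skeletal muscle and Schwann cell markers 1 fell, with the same counts adjusted over each list alone (camera adjusted p = 0.668 for both).

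Among 22 adipogenic regulators 5 rose and 5 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.773). Zfp423 and Pparg rose, while Klf5 (-0.81 ± 0.12) and Egr2 (-0.73 ± 0.09), transcription factors active early in adipogenesis, fell. Of 24 adipocyte lipid genes 5 rose and 2 fell, the same adjusted over the list alone. They included Fabp4 (1.81 ± 0.09), lipoprotein lipase, Lpl (1.31 ± 0.11), and the desaturase Scd1 (0.44), with Fabp5 lower (-0.40). Camera gave an adjusted p = 0.0422 for this list, against adjusted p = 0.202 with an estimated correlation, and the call was also lost on leaving out inguinal GFP- replicate 1 (adjusted p = 0.168), inguinal GFP+ replicate 2 (0.0604) or 3 (0.0912) or epididymal GFP- replicate 1 (0.0523), and after quantile normalization (0.0681). Of 17 fibroblast progenitor markers 6 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0411; adjusted p = 0.202 with an estimated correlation). This call was lost without inguinal GFP+ replicate 2 (adjusted p = 0.0522) or inguinal GFP- replicate 1 or 2 (0.0629 each), and after quantile normalization (0.0506). The coagulation factor receptor F3 (0.55) and decorin, Dcn (0.96), rose and Cd34 fell (-1.13). The receptor Pdgfra also rose (0.38, adjusted p = 0.00995), with an adjusted p = 0.0613 without inguinal GFP- replicate 1 and 0.0553 without inguinal GFP+ replicate 1. Cd34 was no longer called without inguinal GFP+ replicate 1 (adjusted p = 0.0788), inguinal GFP+ replicate 3 (0.0647) or inguinal GFP- replicate 3 (0.076). Interferon response genes were higher as a list (6 of 25 rose and 1 fell; 8 and 1 adjusted over the list alone; camera adjusted p = 0.000971; adjusted p = 0.202 with an estimated correlation), with Bst2 (0.57), Oas1a (0.47) and Ifit2 (0.45) as examples. The list was not called without inguinal GFP+ replicate 2 (adjusted p = 0.0522). The antiviral gene Mx1 was called lower (-0.92, adjusted p = 0.0139), but its mean signal of 5.58 in GFP+ and 24.8 in GFP- cells lies around that of silent genes (18.8 and 17.5), so the value does not measure expression. It was not called without inguinal GFP+ replicate 1 (adjusted p = 0.0503) or inguinal GFP- replicate 2 (0.0549). Cell cycle genes leaned lower, with 3 of 32 called lower, the same adjusted over the list alone (camera adjusted p = 0.0341; adjusted p = 0.798 with an estimated correlation), and the list was not called without inguinal GFP+ replicate 1 (adjusted p = 0.124) or 3 (0.264) or inguinal GFP- replicate 1 (0.168) or 2 (0.0629), or with weakly detected genes left out (0.0529). The called genes included topoisomerase Top2a (-0.15, adjusted p = 0.0204) and cyclin Ccna2 (-0.14, adjusted p = 0.0396). Each lost its call on leaving out any of 4 inguinal arrays in turn (adjusted p up to 0.0939 and 0.186), and with the mean of its probe sets Top2a gave -0.03 (adjusted p = 0.965).

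The remaining lists were not called in inguinal cultures. Of 40 extracellular matrix genes 9 rose and 11 fell (11 and 12 adjusted over the list alone; camera adjusted p = 0.977), among them the collagens Col8a1 (0.73) and Col15a1 (-1.29). Of 36 BMP and TGF-beta pathway genes 3 rose and 8 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.137). Of 27 inflammatory genes 4 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.302), with the chemokines Ccl8 (1.77) and Ccl2 (0.65) among those that rose. Camera gave an adjusted p = 0.754 for the depot position genes (2 of 34 rose and 6 fell), 0.977 for Wnt pathway genes (4 of 34 rose and 5 fell), 0.977 for brown and beige fat genes (2 of 18 rose and 0 fell) and 0.773 for bone and cartilage genes (2 of 22 rose and 4 fell), with the same counts adjusted over each list alone. It gave 0.773 for anti-adipogenic regulators (1 of 17 rose and 3 fell) and 0.977 for the 4 measured sex check genes (none called), again the same adjusted over each list alone. Among depot position genes Hoxd8 fell by 2.39 on the log2 scale. Weaker calls in these lists were Cox7a1, a cytochrome oxidase subunit (0.53, adjusted p = 0.0108; not called without inguinal GFP+ replicate 1, adjusted p = 0.0605, or inguinal GFP- replicate 1, adjusted p = 0.057), Foxc2 (-0.26, adjusted p = 0.0295; not called on leaving out any of 4 inguinal arrays, with adjusted p up to 0.13), Msx1 (-0.70; 0.0508 without inguinal GFP+ replicate 3) and Sox5 (0.83; 0.0665 without inguinal GFP- replicate 1). The endothelial, epithelial, depot position and inflammatory lists had a median and a mean log2 fold change of opposite sign, and the brown and beige list had both below 0 against an upward test direction.

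In epididymal cultures, GFP+ and GFP- cells differed across much of the transcriptome, with genes of the mesothelium, the cell layer that covers abdominal fat, high in GFP- cells. Ebf1, Ebf2, Pparg and Zfp423 were among the single genes high in GFP+ cells. The 8 largest increases were Pla1a (5.77 ± 0.08), a phospholipase, the chemokine Ccl9 (5.17), Ebf2 (5.12 ± 0.10), a transcription factor of fat progenitors, Gpm6b (5.04), laminin alpha 1, Lama1 (4.88), Ms4a4d (4.71), the nuclear receptor Nr2f1 (4.67), and Mrap (4.46). Ebf2 signal was 1174 ± 26.8 in GFP+ and 18.4 ± 5.76 in GFP- cells. The 8 largest decreases were Sfrp2 (-6.00 ± 0.34), Krt7 (-4.67 ± 0.11), Lratd1 (-4.54), Pdlim3 (-4.34), Gpm6a (-4.29), Etl4 (-4.23), Prr15 (-4.20) and the Wnt agonist Rspo1 (-4.14). The limma fit called 5187 of 12393 genes, 2668 higher and 2519 lower in GFP+, and 448 and 394 of them changed by at least 2-fold. After median centring 2290 were higher and 2932 lower.

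The mesothelial list was the single list that camera called here. Of its 15 measured members 14 fell, 0 rose and 1 was not called, the same adjusted over the list alone (camera adjusted p = 2.84e-10; adjusted p = 0.00427 with an estimated correlation). Uroplakin Upk3b fell from 9459 ± 387 in GFP- to 600 ± 22.8 in GFP+ cells (-3.94 ± 0.15), mesothelin, Msln, by 3.58 and Nkain4 by 2.52 on the log2 scale. Of 15 epithelial markers 5 fell and 0 rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.103). Macrophage and leukocyte markers were mixed, with 2 higher, 7 lower and 12 not called of 21 (2 and 8 adjusted over the list alone; camera adjusted p = 0.25). Lyz2 fell by 0.93 and Cd68 by 0.95 on the log2 scale, while Csf1r, the receptor for macrophage colony-stimulating factor, rose (1.06). Mural cell markers had 9 of 20 higher and 4 lower (10 and 4 adjusted over the list alone; camera adjusted p = 0.103), with Mylk (1.84), the receptor Pdgfrb (1.72 ± 0.03) and Myh11 (0.79) among the increases. Of 19 endothelial markers 4 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.663). These included the co-receptor endoglin, Eng (2.81), and the receptor Kdr (-2.98), whose signal was 4469 ± 157 in GFP- cells. Of 13 skeletal muscle and Schwann cell markers 2 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.963).

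Among 22 adipogenic regulators 10 rose and 7 fell (11 and 7 adjusted over the list alone; camera adjusted p = 0.103). Beside Ebf2, Zfp423 and Pparg, the increases included Ebf1 (4.38 ± 0.05), Egr2 (1.92) and Cebpd (0.90), and the decreases Bmp4 (-3.05 ± 0.15), a ligand that promotes commitment to fat. Of 24 adipocyte lipid genes 7 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.551), with Fabp4 (4.30 ± 0.09), the lipase inhibitor G0s2 (2.99) and Fabp5 (1.20) as examples. Anti-adipogenic regulators went both ways, 7 of 17 higher and 9 lower, the same adjusted over the list alone (camera adjusted p = 0.94); Twist2 rose by 3.10 on the log2 scale. Of 17 fibroblast progenitor markers 4 rose and 8 fell, the same adjusted over the list alone (camera adjusted p = 0.103). Cd24a (-2.32), Cd34 (-1.70) and Thy1 (-0.71) fell and F3 rose (0.57), while Dcn (-0.12, adjusted p = 0.622) and Pdgfra (-0.13, adjusted p = 0.298) were not called. Fitted on the epididymal arrays alone Dcn was called lower (adjusted p = 0.0397), and without epididymal GFP- replicate 1 so was Pdgfra (-0.23, adjusted p = 0.044). Extracellular matrix genes had 21 of 40 higher and 14 lower (22 and 14 adjusted over the list alone; camera adjusted p = 0.13). Col14a1 (4.02), Thbs2 (2.73) and Postn (2.35 ± 0.03) rose and Timp3 fell (-0.83). Inflammatory genes had 9 of 27 higher and 10 lower (9 and 11 adjusted over the list alone; camera adjusted p = 0.887); Cxcl14 rose by 4.34 and Il6 by 1.38, and Ccl2 fell by 1.54 on the log2 scale.

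For the other lists camera gave an adjusted p = 0.103 for depot position genes (15 of 34 rose and 9 fell; 15 and 10 adjusted over the list alone), 0.103 for cell cycle genes (17 of 32 rose and 6 fell; 18 and 6), 0.297 for BMP and TGF-beta pathway genes (6 of 36 rose and 14 fell; 6 and 15), 0.553 for Wnt pathway genes (8 of 34 rose and 7 fell; 8 and 7), 0.485 for brown and beige fat genes (4 of 18 rose and 0 fell; 4 and 0), 0.185 for interferon response genes (8 of 25 rose and 2 fell; 10 and 2), 0.663 for bone and cartilage genes (3 of 22 rose and 3 fell; 2 and 3) and 0.25 for the sex check genes (0 of 4 rose and 2 fell; 0 and 2), the second pair of counts being adjusted over the list alone each time. Among brown and beige fat genes Cox7a1 rose (0.50) and so did Klhl13 (0.11, adjusted p = 0.00942), which was not called after median centring (adjusted p = 0.119) or without epididymal GFP- replicate 3 (0.0546). Pax7, from the skeletal muscle and Schwann cell list, was called higher (0.92, adjusted p = 0.014; 0.0863 without epididymal GFP+ replicate 1) at a mean signal of 30.9 in GFP+ and 7.66 in GFP- cells, near that of silent genes (21.4 and 20.7), so this value is no measure of expression either. The Y-linked Kdm5d fell (-0.21, adjusted p = 0.0282), and was not called on leaving out any of 5 epididymal arrays, with adjusted p up to 0.129. In the BMP and TGF-beta list the activin subunit Inhbb rose by 3.45 on the log2 scale, whereas its second probe set gave 0.31. The anti-adipogenic, adipocyte lipid, skeletal muscle and Schwann cell, inflammatory and bone and cartilage lists had a median and a mean of opposite sign.

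**Figure D3:**
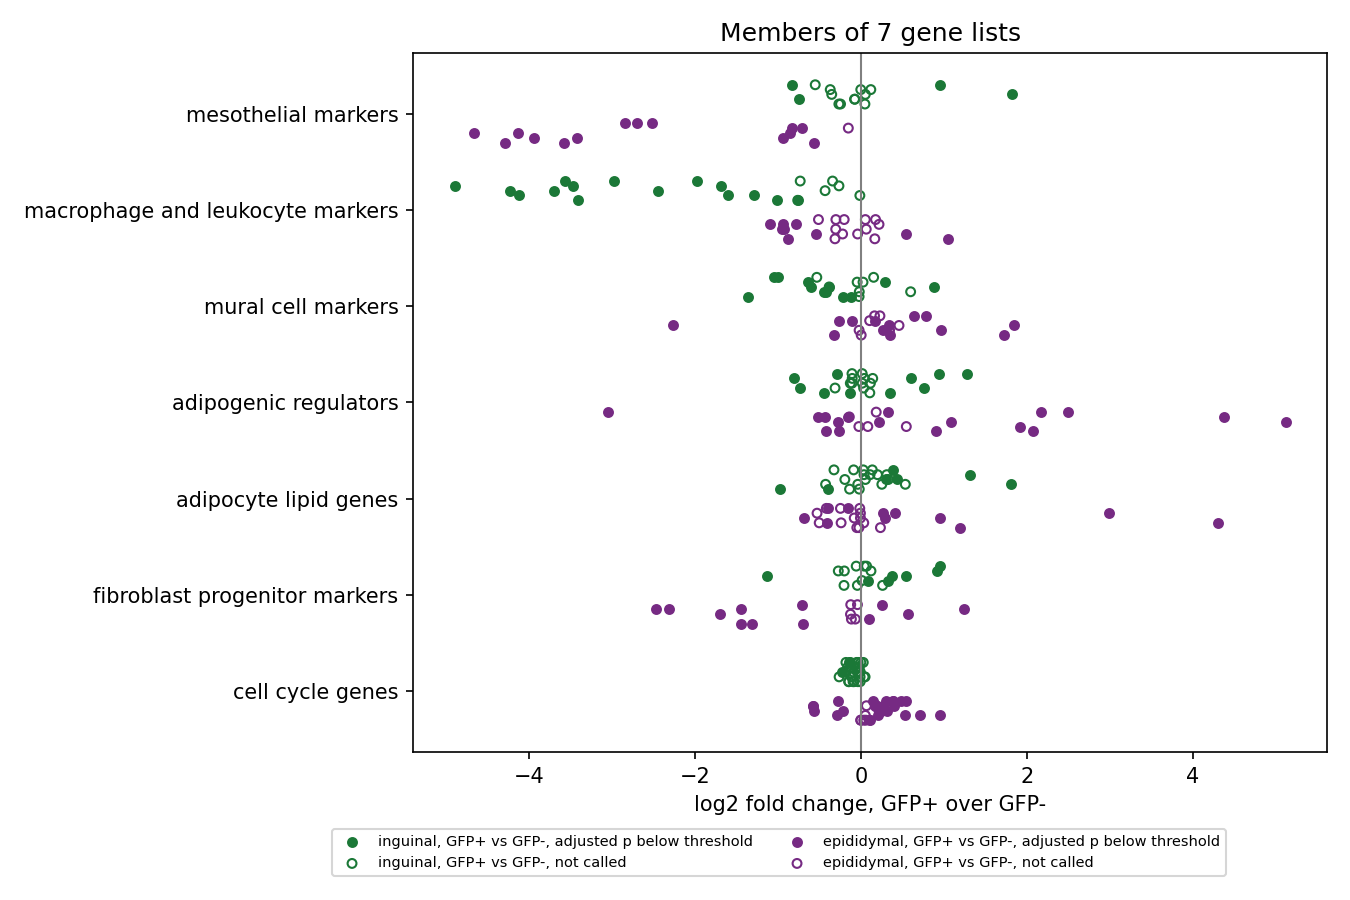
Log2 fold change, GFP+ over GFP-, of each measured member of 7 gene lists, in inguinal (green) and epididymal (purple) cultures; filled points passed an adjusted p of 0.05 in limma and open points did not. Macrophage and leukocyte markers reach -4.90 in inguinal cultures, mesothelial markers reach -4.67 in epididymal cultures, and adipogenic regulators spread to both sides.

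Some genes moved the same way with GFP in both depots, among them Mrap, Fabp4 and Pparg, which rose, and Igfbp2, an insulin-like growth factor binding protein, which fell. The genes with the largest smaller change were, for increases, Mrap (3.44 in inguinal and 4.46 in epididymal cells), Spon1 (2.07 and 3.16), Cyp7b1 (2.02 and 3.02), Fabp4 (1.81 and 4.30), the R-spondin receptor Lgr6 (1.75 and 2.37), Ggt5 (2.18 and 1.69), the dipeptidase Dpep1 (1.67 and 3.74) and the progesterone receptor Pgr (1.66 and 1.92). A second, dimmer probe set of Spon1 gave 0.14 and 0.50. Weakly detected probe sets also gave less for Mrap (0.15 and 0.20) and Fabp4 (0.81 and 0.43, and 0.39 and 0.35), while a brighter one of Fabp4 gave 1.92 and 4.23. For decreases the genes with the largest smaller change were the glutathione transferase Gsta4 (-2.17 and -2.55), Igfbp2 (-2.44 and -2.04), Gatm (-1.42 and -2.03), an enzyme of creatine synthesis, the kinase Tec (-1.35 and -1.99), the transcription factor Nfib (-1.35 and -1.42), Klhdc8a (-1.33 and -2.36), cardiac troponin T, Tnnt2 (-1.27 and -3.59), and Ctss (-4.63 and -1.23). For Nfib another bright probe set gave -1.37 and -1.50, and weakly detected ones gave 0.01 and 0.11, and 0.02 and -1.80. In all, 285 genes were higher and 335 lower in GFP+ cells of both depots, where 140 and 184 would be shared by independent calls (odds ratio 3.05, 95% interval 2.59 to 3.59, Fisher's exact test p = 5.38e-39, two-sided, adjusted p = 2.15e-38 over 4 overlaps; odds ratio 2.51, 2.17 to 2.90, p = 9.31e-34, adjusted p = 1.86e-33). Fisher's test treats genes as independent, which they are not, so these p-values may overstate the evidence. Opposite calls also exceeded independence, so the excess was not confined to a shared direction. There were 206 genes higher in inguinal and lower in epididymal GFP+ cells against 133 (odds ratio 1.88) and 298 the other way against 195 (odds ratio 1.89). Across all genes, which are not independent replicates, the log2 fold changes of the depots correlated at Pearson r = 0.083 and Spearman rho = 0.039. These comparisons share no arrays.

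**Figure D4:**
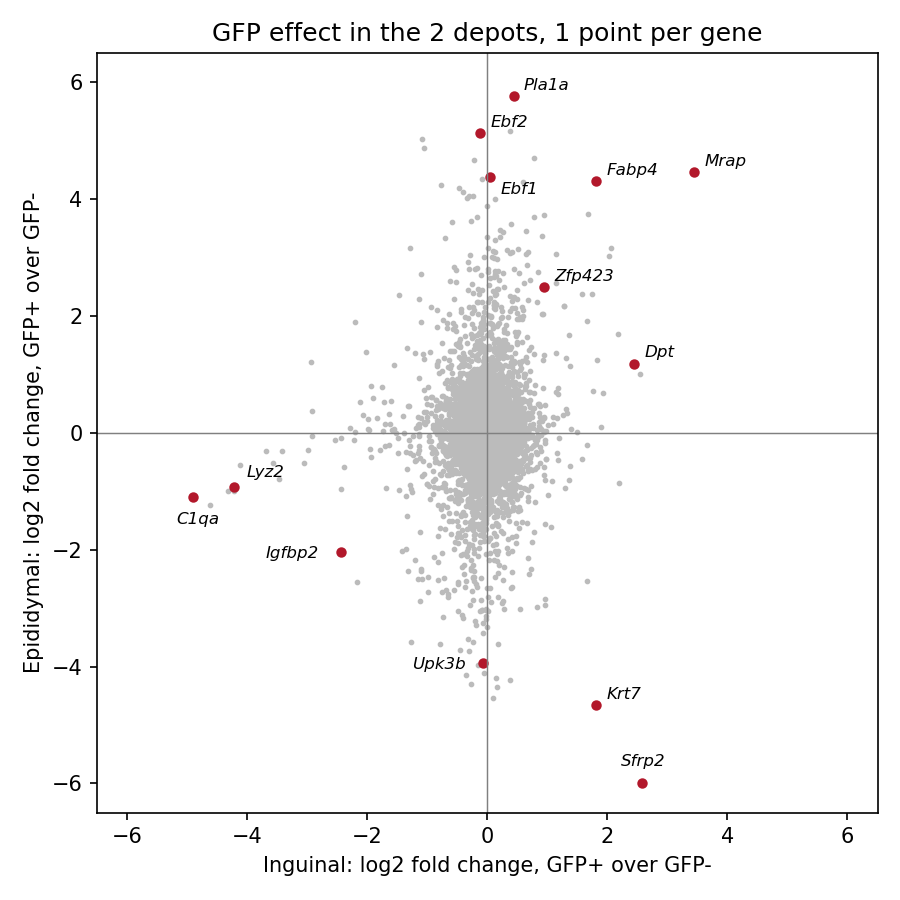
Log2 fold change of GFP+ over GFP- cells in inguinal cultures (horizontal axis) and epididymal cultures (vertical axis), 1 point per gene, with 13 genes named. Mrap, Fabp4 and Zfp423 lie above 0 on both axes, Igfbp2 below 0 on both, and Sfrp2 at 2.57 and -6.00.

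The GFP contrast itself differed between depots for 4313 genes (interaction, limma adjusted p under 0.05), 2000 with a higher and 2313 with a lower value in inguinal cells. After centring each array on its median the split was 2451 and 1880. The 6 genes with the smallest p were Mustn1 (-4.66 ± 0.07), Ebf1 (-4.34), the integrin Itga9 (-4.53), the retinaldehyde dehydrogenase Aldh1a1 (4.18), Nr2f1 (-4.89) and Epb41l3 (-2.59). Ebf1 signal was 3577 ± 59.9 and 3477 ± 90.3 in inguinal GFP+ and GFP- cells, 2919 ± 169 in epididymal GFP+ and 125 ± 5.75 in epididymal GFP- cells, so the epididymal GFP- cells stood apart. Sfrp2 rose with GFP in inguinal and fell in epididymal cells, a difference of 8.57 ± 0.48, and Krt7 did likewise, with a difference of 6.48 ± 0.16. As lists, mesothelial markers (12 of 15 higher and 0 lower, the same adjusted over the list alone; camera adjusted p = 1.36e-09) and macrophage and leukocyte markers (0 of 21 higher and 15 lower; 0 and 17 adjusted over the list alone; camera adjusted p = 1.05e-07) differed between depots. Both held with an estimated correlation, at adjusted p = 0.00541 and adjusted p = 0.0287. Several mesothelial markers were weakly detected in both inguinal groups, such as Upk3b (10.5 in GFP+ and 12.5 in GFP- cells). For these the difference reflects the fall in epididymal cells. Mural cell markers (3 of 20 higher and 12 lower; camera adjusted p = 0.000444) and fibroblast progenitor markers (10 of 17 higher and 1 lower; camera adjusted p = 0.00378) did not hold, each at adjusted p = 0.0527 with an estimated correlation. Depot position genes (6 of 34 higher and 15 lower; camera adjusted p = 0.0188) gave adjusted p = 0.185 with an estimated correlation, and cell cycle genes (5 of 32 higher and 18 lower; camera adjusted p = 0.0223) gave adjusted p = 0.739 with an estimated correlation and were no longer called without inguinal GFP+ replicate 3 (adjusted p = 0.0534) or epididymal GFP- replicate 1 (adjusted p = 0.058) or with weakly detected genes left out (0.0633). These 4 lists had the same counts adjusted over each list alone. Median, mean and test differed in sign for the anti-adipogenic, adipocyte lipid, BMP and TGF-beta, Wnt, inflammatory, interferon response and bone and cartilage lists, none of them called.

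The GFP+ cells of the depots differed strongly. A batch of cultures or arrays that followed depot could not be told apart from it. Inguinal GFP+ cells carried Dkk2 (7.47 ± 0.26), a Wnt antagonist, the ribosomal protein paralogue Rpl39l (7.32), the limb homeobox gene Shox2 (6.01), Igfbp5 (5.42), Rspo2 (4.90), the transcription factor Tbx15 (4.55), the gap junction gene Gjb2 (4.32) and the granzyme Gzme (4.07). Higher in epididymal GFP+ cultures were haptoglobin, Hp (-5.65 for inguinal minus epididymal), the Wilms tumour factor Wt1 (-5.60 ± 0.14), the histamine receptor Hrh4 (-5.22), the transcription factor Tcf21 (-4.93), serum amyloid Saa3 (-4.92), the kinase Stk26 (-4.64), Wnt4 (-4.56) and Upk3b (-4.54). Upk3b read 600 in epididymal GFP+ and 9460 in epididymal GFP- cells. Mesothelial cells carried into the GFP+ sort, taken up in the closing section, stay open as a candidate explanation for such markers. Dkk2 signal was 6455 ± 440 in inguinal and 21.2 ± 8.73 in epididymal GFP+ cells, the latter at the level of silent genes, so that its difference is not an exact size. Wt1 was 61.8 ± 4.60 and 3764 ± 75.7. The limma fit called 6292 genes, 2922 higher and 3370 lower in inguinal cells, a balance that turned to 3214 and 2750 after quantile normalization and to 3275 and 2973 after median centring. Weakly detected genes leaned lower: the 30% of genes with the lowest mean had a median log2 difference of -0.16, and with those genes left out before the test 2896 were called higher and 2974 lower. Of 104 genes of families silent in fibroblasts 2 were called higher and 14 lower, so some calls between depots need not reflect expression.

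Cell cycle genes were higher in inguinal GFP+ cells, 28 of 32 with 2 lower, the same adjusted over the list alone (camera adjusted p = 4.17e-12; adjusted p = 0.148 with an estimated correlation), for example Tk1 (1.22), Mcm3 (0.94) and the replication clamp Pcna (0.65). Other Mcm3 probe sets gave 1.03, 0.87, 0.54 and -0.06. Mural cell markers were lower, 13 of 20 with 2 higher, the same adjusted over the list alone (camera adjusted p = 3.78e-05; adjusted p = 0.041 with an estimated correlation), led by desmin, Des (-2.86, but -0.68 with a second, dimmer probe set), Myh11 (-2.35) and Smtn (-2.08). Mesothelial markers were lower, 11 of 15 with 2 higher (camera adjusted p = 0.000134; adjusted p = 0.041 with an estimated correlation), and so were BMP and TGF-beta pathway genes, 21 of 36 with 5 higher (camera adjusted p = 0.000766; adjusted p = 0.041 with an estimated correlation), both with the same counts adjusted over the list alone. Bmp4 (-4.13), the inhibitor Id4 (-2.27) and the receptor Tgfbr1 (-1.42) were lower in inguinal cells. Depot position genes split 10 higher and 19 lower of 34, the same adjusted over the list alone (camera adjusted p = 0.0693), with Hoxa5 (-3.44) lower in inguinal cells. The chemokine Ccl7 (2.15) and the lipid droplet protein Plin2 (0.98) were higher and the proteoglycan lumican, Lum (-3.26), lower in inguinal cells. The epithelial factor Grhl2 (-0.65, adjusted p = 0.0143) and the bone factor Dlx5 (-0.62) were lower too; after quantile normalization neither was called (adjusted p = 0.15 and 0.0882), and without inguinal GFP+ replicate 1 Grhl2 was not (0.0731). Pparg was higher in inguinal than in epididymal GFP+ cells (1.90 ± 0.14), and Zfp423 was lower (-0.88 ± 0.18). The brown fat gene Lhx8 was higher in inguinal cells (3.80), where 3 of 18 brown and beige fat genes were higher and 6 lower, the same adjusted over the list alone (camera adjusted p = 0.583). The epithelial list, not called, had a median and a mean of opposite sign.

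The GFP- cells of the depots differed in mesothelial genes, as the GFP+ cells did. Inguinal GFP- cells were higher in Rpl39l (7.0), Dkk2 (6.15), Shox2 (5.61), Gzme (5.52), Gjb2 (5.40), Pla1a (5.32 ± 0.08), the growth factor Fgf7 (5.18) and Igfbp5 (5.11). Epididymal GFP- cells were higher in Upk3b (-8.41 ± 0.15), Bnc1 (-7.96), Stk26 (-7.61), Bmp4 (-7.20), Rspo1 (-7.04), clusterin, Clu (-7.0), the adhesion receptor Cxadr (-6.49) and Sfrp2 (-6.45). In inguinal GFP- cells Upk3b read 12.5 and Bnc1 26.7, near the level of silent genes (17.5), so the sizes and order of these differences rest on the floor and the pseudocount. The limma fit called 6656 genes, 3399 higher and 3257 lower in inguinal cells, or 3200 and 3413 after median centring. Of the 6656, 1995 were higher and 1986 lower in the GFP+ comparison too, where independent calls would share 801 and 886. Mesothelial markers were lower in inguinal GFP- cells, 13 of 15 with 1 higher, the same adjusted over the list alone (camera adjusted p = 2.47e-09; adjusted p = 0.00664 with an estimated correlation). Macrophage and leukocyte markers were higher, 15 of 21 with 1 lower, the same adjusted over the list alone. Camera gave an adjusted p = 0.000154 for this list, and adjusted p = 0.105 with an estimated correlation. Examples were C1qc (3.57), Lyz2 (2.29) and Csf1r (1.89, with 1.51 and 0.18 from other probe sets). Cell cycle genes were higher, 28 of 32 with 1 lower (28 and 2 adjusted over the list alone; camera adjusted p = 1.85e-10; adjusted p = 0.159 with an estimated correlation), with Tk1 (1.29), the kinases Aurka (1.02) and Plk1 (0.97) as examples. Extracellular matrix genes were higher, 24 of 40 with 8 lower (24 and 9 adjusted over the list alone; camera adjusted p = 0.00689; adjusted p = 0.672 with an estimated correlation), BMP and TGF-beta pathway genes lower, 20 of 36 with 7 higher (21 and 7 adjusted over the list alone; camera adjusted p = 0.00689; adjusted p = 0.105 with an estimated correlation), and fibroblast progenitor markers lower, 10 of 17 with 3 higher, the same adjusted over the list alone (camera adjusted p = 0.0343; adjusted p = 0.159 with an estimated correlation). Postn (2.48) and Thbs2 (2.78) were higher and the peptidase Dpp4 (-4.87) and the adhesion molecule Icam1 (-3.82) lower in inguinal GFP- cells. The inhibitor Id2 was lower (-2.78, and -2.76 with another probe set), although a further, dimmer probe set gave -0.39. The neural crest factor Sox10 was higher (0.53, adjusted p = 0.0276), a call lost on leaving out any of 4 arrays (adjusted p up to 0.0985) and on averaging its probe sets, where it turned to -0.17 (adjusted p = 0.492). Kdm5d was higher (0.23, adjusted p = 0.0141; 0.0794 without inguinal GFP- replicate 2 and 0.0771 without epididymal GFP- replicate 1). The anti-adipogenic, brown and beige fat and mural cell lists, not called, had a median and a mean of opposite sign. Zfp423 was higher in inguinal than in epididymal GFP- cells (0.68 ± 0.18, adjusted p = 0.0044).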

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

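The tests of a second macrophage list, of a lower fibroblast share, of the spread between arrays and of dilution were chosen after the results were seen. The single genes and their count were picked because the GFP effect differed between depots, by the interaction test of limma with Benjamini-Hochberg adjustment, and the lists by camera on the same contrast. The counts of single comparisons and the last patterns below were not picked by that test. The difference, inguinal minus epididymal log2 fold change, was called for 4313 genes. In 100 drawn splits with GFP labels permuted within each depot the real split gave the largest count, in 1 of 100 splits. The highest other was 3451. Such permuting also removes the GFP effect within each depot. The result thus goes against random GFP labels, but it cannot test whether the effect differs between depots. For the 6 lists the real split also gave the most, in 1 of 100 splits, but the highest other was 5. That margin is thin, since 5 lists were called without inguinal GFP+ replicate 3 and 2 with an estimated correlation, so the number of lists is not set apart from chance. For the genes shared by both depots, 285 higher and 335 lower, each in 1 of 100 splits, the highest others were 1 and 0, since nearly all drawn splits shared no gene. That comparison says nothing on sharing beyond the calls within each depot.

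For the single comparisons the 10 splits of 6 arrays are too few for a share under 0.05. The real counts and the highest others were 1556 and 1 for inguinal GFP, 5187 and 0 for epididymal GFP, 6292 and 0 for the depots in GFP+ and 6656 and 0 in GFP- cells, each in 1 of 10 splits. For called lists they were 6 and 5, 1 and 2, 4 and 4, and 6 and 5, in the same order, with as many lists in 1, 10, 2 and 1 of 10 splits.

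The mean difference over a list was 2.38 for mesothelial markers, -1.81 for macrophage and leukocyte markers, 0.72 for fibroblast progenitor markers, -0.54 for mural cell markers, -0.25 for depot position genes and -0.22 for cell cycle genes. The last 4 lost their call: fibroblast progenitor and mural cell markers gave adjusted p = 0.0527 with an estimated correlation, depot position genes adjusted p = 0.185 and cell cycle genes adjusted p = 0.739.

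Among single genes the contrast was higher in inguinal cells for Sfrp2 (8.57), Krt7 (6.48), Lratd1 (4.64), Etl4 (4.61), Pdlim3 (4.5), Prr15 (4.36), Gpm6a (4.03), Upk3b (3.87), Kdr (3.81), Rspo1 (3.79), Bnc1 (3.79) and Msln (3.33). Values from 3.06 down to 2.05 were those of Bmp4 (3.06), Trpc6 (3.05), Cxadr (3.0), Stk26 (2.98), Clu (2.81), Dpp4 (2.59), Tnnt2 (2.31), Ccl2 (2.20) and Cd24a (2.05). Smaller ones were Icam1 (1.71), Nkain4 (1.69), Col8a1 (1.63), Rspo2 (1.53), Dkk2 (1.32), Dpt (1.27), Id2 (1.21), Bst2 (1.18), Saa3 (1.09), Dcn (1.08), Ccl8 (1.06) and Klhdc8a (1.04). The smallest were Lpl (0.90), Thy1 (0.78), Sox5 (0.78), Tec (0.64), Wt1 (0.62), Des (0.55), Pdgfra (0.50), Oas1a (0.42), Plin2 (0.38), Timp3 (0.33), Ccl7 (0.33), Scd1 (0.14) and Klhl13 (0.12).

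It was lower in inguinal cells for Gpm6b (-6.13), Lama1 (-5.94), Pla1a (-5.33), Ebf2 (-5.25), Nr2f1 (-4.89), Ccl9 (-4.79), Mustn1 (-4.66), Itga9 (-4.53), Col15a1 (-4.45), Cxcl14 (-4.42), Col14a1 (-4.36) and Ebf1 (-4.34). Next came Ms4a4d (-3.94), Fgf7 (-3.88), C1qa (-3.79), C1qc (-3.58), Ctss (-3.39), C1qb (-3.39), Lyz1 (-3.32), Lyz2 (-3.29), Mpeg1 (-3.21), Tyrobp (-3.05) and Eng (-3.02). Values from -2.97 to -2.07 were those of Twist2 (-2.97), G0s2 (-2.88), Inhbb (-2.81), Egr2 (-2.65), Epb41l3 (-2.59), Hp (-2.58), Fabp4 (-2.49), Mylk (-2.23), Postn (-2.22), Thbs2 (-2.20) and Dpep1 (-2.07). Smaller ones were Pdgfrb (-1.84), Csf1r (-1.81), Hoxd8 (-1.80), Myh11 (-1.78), Tgfbr1 (-1.69), Il6 (-1.67), Fabp5 (-1.59), Zfp423 (-1.56), Mx1 (-1.54), Gzme (-1.45), Gjb2 (-1.08), Hrh4 (-1.08), Mcam (-1.04), Cebpd (-1.03), Mrap (-1.02) and Cyp7b1 (-1.01). The smallest were Actg2 (-0.94), Pparg (-0.89), Smtn (-0.75), Cd68 (-0.75), Msx1 (-0.72), Foxc2 (-0.71), Id4 (-0.69), Lgr6 (-0.62), Hoxa5 (-0.57), Plk1 (-0.44), Ccna2 (-0.44), Aurka (-0.36), Top2a (-0.29) and Pcna (-0.15). The value of Mx1 rests on signal around the level of silent genes in inguinal cells and does not measure expression there. Several mesothelial genes were also weakly detected in both inguinal groups. Signals in inguinal GFP+ and GFP- cells were 10.5 and 12.5 for Upk3b, 8.41 and 15 for Rspo1, 28.8 and 38.9 for Gpm6a and 37.2 and 47.3 for Msln. The higher contrast of these genes in inguinal cells reflects their fall in epididymal cells. Krt7 (564 and 148) was not among them.

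Of the genes checked for the other observations, some of them named in the report too, the contrast was higher in inguinal cells for Aldh1a1 (4.18), Krt8 (3.35), Cyp26a1 (2.32), Krt18 (2.15), Igfbp3 (2.09), Aldh1a2 (2.03), Crabp1 (1.88), Irs1 (1.39), Dlk1 (1.28), Plagl1 (0.98), Igf1 (0.90), Meg3 (0.70), Grb10 (0.66) and Gatm (0.61). It was lower for Aldh1a3 (-4.16), Rarb (-3.25), Dhrs3 (-2.34), Rbp4 (-1.50), Igfbp2 (-0.40) and Igfbp4 (-0.34).

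Macrophage and leukocyte markers were lower in inguinal GFP+ than in GFP- cells, at a median log2 fold change of -1.69. Leukocytes among the cultured inguinal GFP- cells, where Lyz2 reached 4011, stay open as a candidate explanation. A second list of macrophage genes had a median of -0.53 (camera adjusted p = 0.00873 with an estimated correlation; 18 of 36 not called), but it holds 2 of the leading genes and cannot tell leukocytes from expression by GFP- fibroblasts. A lower fibroblast share that raises every other cell type stays open: the leukocyte median differed by -1.62 from that of endothelial and mesothelial markers, but 23 of those 34 markers were weakly detected in inguinal GFP- cells and could hardly fall. Mural cell markers, 5 of 20 of them weakly detected, were lower in GFP+ too (camera adjusted p = 0.0219 with an estimated correlation). Their median was -0.30, against -1.69 for leukocyte markers. Some mural genes were bright over all arrays, with mean log2 values of 13.39 and 11.13 for other probe sets of Mylk and Pdgfrb. Any signal of the fibroblasts themselves would shrink their fall, so the smaller median cannot decide on an equal rise of every other cell type.

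More genes were called in epididymal than in inguinal cultures. Scaling between arrays is argued against, since the ratio of the counts was 3.37 after quantile normalization. The ratio of within-group SDs, epididymal over inguinal, was 1.04. It is no test of a smaller epididymal spread as the cause. All groups share an estimate of the spread per gene in the fit, so such a spread could not by itself favour epididymal calls. Dilution of GFP+-like cells by mesothelial cells that make up less than 50% of the GFP- RNA is argued against as the whole cause: 323 genes, 12.1% of those called higher, had a 95% interval wholly above 2-fold. A larger mesothelial share, or a difference between the fibroblasts of the depots, stays open.

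Weakly detected genes read lower on inguinal arrays, with a median log2 difference of -0.16 in GFP+ and -0.11 in GFP- cells. An offset at low signal could account for this: 104 genes of families silent in fibroblasts, such as olfactory receptors, had medians of -0.14 (95% interval -0.25 to -0.01) and -0.16 (-0.25 to -0.04). Both intervals reach past the bound of -0.1 set for the test, so the evidence is weak. They come from resampling the genes with the arrays held fixed. The intervals thus treat genes as independent and measure no spread between arrays. Between depots 2 of the 104 genes were called higher and 14 lower in GFP+ cells, and 1 and 12 in GFP- cells. With GFP 0 were called in inguinal cultures, and 2 higher and 0 lower in epididymal cultures. A biological explanation for the lower values was not tested.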

How the results depend on the processing

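Counts without the leukocyte or mesothelial lists were chosen after the data were seen. They were 1523 for inguinal and 5173 for epididymal GFP, against 1556 and 5187. These counts only drop the listed genes from the calls, with no new fit. They cannot test whether the remaining calls come from leukocytes or mesothelial cells. Counts of called genes moved by over 1.5 times only under stricter thresholds, by construction: with at least 1.5-fold they were 392 (inguinal GFP), 1677 (epididymal GFP), 1744 (interaction), 2193 (depots in GFP+), 2687 (depots in GFP-) and 60 higher and 73 lower in both depots, and at an adjusted p of 0.01 they were 963 for inguinal GFP and 167 and 194 in both depots. Median centring moved the share of higher calls from 46.4% to 56.6% in the interaction, 41.9% to 51.6% in inguinal GFP, 51.4% to 43.9% in epididymal GFP, 46.4% to 52.4% between depots in GFP+ and 51.1% to 48.4% in GFP-. Leaving out an array gave 1158 to 1845, 4733 to 5313, 3897 to 4317, 5698 to 6290 and 6088 to 6781 genes in that order, 200 to 339 higher and 248 to 383 lower in both depots, and 3 to 6, 1 to 1, 5 to 7, 4 to 6 and 6 to 6 lists; the 3 came without inguinal GFP- replicate 1. With an estimated correlation 2 lists were called for inguinal GFP, 2 for the interaction and 1 for the depots in GFP-. Fry, which does not compare a list with other genes, called 18 for epididymal GFP, 16 for the interaction, 16 in GFP+ and 17 in GFP-, and without weakly detected genes 3 were called in GFP-. Fry gave the opposite direction for lists that camera had not called: in epididymal GFP for anti-adipogenic (adjusted p = 0.00182) and inflammatory genes (0.00374), in the interaction for adipocyte lipid (0.00631) and BMP and TGF-beta genes (0.000661), and in the depots in GFP- for anti-adipogenic (0.00144), adipocyte lipid (0.00235), mural cell (0.000743) and Wnt genes (5.48e-05). For Sox10 the depot difference in GFP- cells turned to -0.17 with the mean of its probe sets, which disagree. For the other shifts the cause was not tested.

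Of 259 gene values in the text, 229 kept their direction and side of the threshold under every alternative run and 30 did not. The 30 differed in size. In inguinal GFP they included small changes, such as Ccna2 (-0.14), Top2a (-0.15) and Eng (-0.21). Larger ones included Msx1 (-0.70), Sox5 (0.83), Mx1 (-0.92) and Cd34 (-1.13). Genes at low signal are limited by the background of the arrays.

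With the replicate number as a block the counts were 1528, 5154, 4220, 6245 and 6628, with 272 higher and 328 lower in both depots. With the block within depot they were 1466, 5119 and 4158, with 266 and 321. Over all genes the numbers showed little pairing: deviations of same-numbered arrays correlated between -0.057 and 0.044, and 3 of 12 arrays correlated best with their own number. On the first principal components, however, same-numbered inguinal arrays shifted together, with GFP- minus GFP+ at 3.91, 3.88 and 3.94 on the first and 1.08, 1.11 and 1.07 on the second, the closest of 6 orderings. In epididymal cells 4 of 6 orderings were as close. Whether the inguinal arrays were paired stays open.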

Other observations

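The test of a carried-over mesothelial share, and the lists of retinoid, imprinted, IGF axis and further macrophage genes with the genes named from them, were chosen after the leading genes were seen. The retinaldehyde dehydrogenases, which make retinoic acid, went different ways: Aldh1a1 rose by 1.66 in inguinal GFP+ cells and fell by 2.53 in epididymal ones, Aldh1a2 rose by 1.58 and fell by 0.45, and Aldh1a3 fell by 2.94 and rose by 1.22 on the log2 scale. In epididymal cells the receptor Rarb (3.47), the reductase Dhrs3 (1.98) and the carrier Rbp4 (2.10) rose and Cyp26a1, which breaks down retinoic acid, fell (-2.54). Crabp1 rose in inguinal cells (1.67), and Rarres2 rose in both (1.38 and 1.14). In inguinal cells Rarb (0.21) and Dhrs3 (-0.37) were not called. Of 20 measured retinoid genes 6 rose and 1 fell in inguinal cells (camera adjusted p = 0.00839; adjusted p = 0.121 with an estimated correlation), and 9 rose and 4 fell in epididymal cells, where the list was not called (camera adjusted p = 0.186).

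The insulin-like growth factor binding proteins Igfbp2 (-2.44 and -2.04) and Igfbp4 (-1.09 and -0.75) fell in inguinal and epididymal GFP+ cells. Igf1 (0.24 and -0.66) and the insulin receptor substrate Irs1 (0.75 and -0.64) rose in inguinal and fell in epididymal cells, and Igfbp3 fell in epididymal cells (-1.52) and was not called in inguinal cells (0.58, adjusted p = 0.191). Igfbp5 rose in both (0.59 and 0.27), but with the mean of its probe sets neither was called (adjusted p = 0.213 and 0.17). Of 18 IGF axis genes 5 rose and 2 fell in inguinal cells (camera adjusted p = 0.12) and 5 rose and 9 fell in epididymal cells (camera adjusted p = 0.168), and the list was called in neither. Among imprinted genes Plagl1 fell in both (-1.20 and -2.19), Dlk1 fell in epididymal cells (-1.07), and Grb10 (-0.09 and -0.76) and Meg3 (-0.19 and -0.89) fell in both. The inguinal calls of Grb10 and Meg3 did not hold with the mean of their probe sets (adjusted p = 0.533 and 0.0967). Of 22 imprinted genes 2 rose and 4 fell in inguinal cells (camera adjusted p = 0.547) and 2 rose and 7 fell in epididymal cells (0.0773), called in neither, and 9 had a higher and 2 a lower contrast in inguinal than in epididymal cells (camera adjusted p = 0.0344; adjusted p = 0.123 with an estimated correlation). Of 36 further macrophage genes 16 fell and 2 rose in inguinal GFP+ cells (camera adjusted p = 4.98e-11, or 0.00873 with an estimated correlation). This list holds 2 of the leading inguinal genes, so it is no independent support for their fall.

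Mesothelial genes were still detected in epididymal GFP+ cells, and mesothelial cells carried into the GFP+ sort at a single share were tested as a candidate explanation. The signal in GFP+ as a percentage of that in GFP- cells had a median of 8.92% over 11 abundant markers, among them Krt8 (8.92%) and Krt18 (15.1%). A single share is argued against for the whole list, since 2 markers lay more than 3-fold from the median beyond their error, Wt1 at 67.3% and Efemp1 at 52.2%. These 2 may also be made by the epididymal fibroblasts themselves. The other 9 ran from 3.06% (Krt7, weakly detected at 56.1 in GFP+ cells) to 16.6% (Nkain4). That spread lies within the 3-fold bound around the median, so the test does not decide on a single share for these 9.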
